A study of Homo sapiens with 18 samples.

How the data were processed

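Total RNA from SNU-449 cells, a human hepatocellular carcinoma line, was measured on 18 single-colour Agilent arrays, with Cy3 as the label. The labels placed the arrays in 6 groups of 3. Cells had received a FAM-labelled negative control siRNA (siNC) or 1 of 2 siRNAs against FOXS1 (siFOXS1-1 and siFOXS1-2) at 50 nM. Each siRNA was combined with recombinant TGFβ1 at 1 ng/mL or with BSA alone for 72 h. The labels call the samples of a group replicates but do not say that they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

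The deposited scanner files hold 1 array each. Their processed signal is an intensity that the authors obtained with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes, with background subtraction and detrending but no scaling between arrays, per the file headers. The deposited files also give the raw median intensity of each spot and of its local background, per the file headers. A deposited table of the whole series holds log2 values that the authors made from the same arrays. It has 26637 probes, and its values behave as log2 values scaled to each array's 75th percentile and centred per probe on a baseline that is not given in the sources used here. The column medians of that table lay between -0.0179 and 0.0175. Differences between its columns correlated with the differences computed here at 0.903 to 0.960, with slopes of 1.03 to 1.08. It was used only as an alternative source of values.

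The 50599 probes that are not controls were matched through their RefSeq accessions, without version numbers, to a gene table of assembly GRCh38.p14. That gave a symbol to 28174 probes (55.7%) and 20503 genes. The array annotation was built on hg19, so the gene table was used for names only and no coordinates are given. Each processed signal was divided by the 75th percentile of its array and converted to log2. Values below 0.0452 of the 75th percentile, -4.47 on the log2 scale, were set to that floor. Where no array of a group was above background for a gene, the fold change is given as a lower bound, computed against the dimmest spot called well above background on those arrays. Spots that Feature Extraction marked as outliers were left out. A probe was kept when Feature Extraction called it well above background on all 3 arrays of at least 1 group, which left 26582 probes. Of these, 19531 had a symbol and 7051 did not. Each gene was represented by its detected probe with the highest mean, which gave 14486 genes, of which 27 had a missing value on some array. The number of arrays, not a depth, limits the precision.

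One linear model with the 6 group means was fitted to all 18 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with version 1.17.8 of data.table. It gave 11 comparisons. These were TGFβ1 against BSA with each siRNA, each FOXS1 siRNA against siNC in BSA and in TGFβ1, the 2 FOXS1 siRNAs against each other in each treatment, and the interaction of TGFβ1 with each FOXS1 siRNA. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes of the comparison. Every adjusted p of a gene in the text comes from limma, two-sided, with 3 arrays in each group, and every ± is the model's standard error of a log2 difference.

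The 30 gene lists, the rule for naming genes, the comparisons and most alternatives were fixed before the data were examined. The lists held 726 entries, of which 601 were measured. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 30 lists of a comparison, and again with a correlation estimated from the data. That correlation was estimated in the model without a term for the slides, so spread shared within a slide enters it. A call lost with it therefore does not show that a list was unchanged. Calls of single members were made over all genes and also adjusted over the list alone. The size of the TGFβ1 response was compared between siRNAs with limma's fry, which asks whether a set moves one way on balance and does not compare it with other genes. Its adjusted p covers the 2 siRNAs, and its calls in the alternatives use the unadjusted p. The named genes were FOXS1, the 12 highest and 12 lowest with TGFβ1 in siNC cells, and, for each treatment, the 8 highest and 8 lowest that both FOXS1 siRNAs changed in 1 direction, ranked by the smaller change. The rule added the 5 highest and 5 lowest of each FOXS1 siRNA and of TGFβ1 within each FOXS1 siRNA, the 4 and 4 of the direct comparisons, the 6 and 6 of the interactions, and up to 4 members of each list with the smallest adjusted p or the opposite sign. A named gene had to be called, to have no overlap between the values of the compared groups (chance gives that in 10% of comparisons of 3 with 3), to be above background on all arrays of a group, and to have all its detected probes on 1 side of 0. List members were exempt from those conditions. Some genes that met the rule are not named in the text. Probes for near-identical copies (LEFTY1, CGB3 and AMY1C) cannot be assigned to 1 copy with certainty. Of 230 called genes with several probes in the TGFβ1 comparison of siNC cells, 17 had probes of opposite sign, and 208 of 1389 did for siFOXS1-1 in BSA.

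The replicate number in the labels was also the slide, and each of the 3 slides held all 6 groups in the same positions. Position on the slide and group therefore cannot be told apart. To check whether the numbers pair the samples, each group's mean was subtracted and the arrays were correlated over 14459 genes. The 45 pairs of arrays with 1 number in common had correlations of 0.408 to 0.839, and the other pairs -0.648 to 0.273. All 18 arrays correlated best with an array of their own number. A model with the replicate number as a further term (the replicate block) was therefore fitted beside the main one. Its value is given where it changes the call of a list, a named gene or a FOXS1 difference, or a count over a whole comparison. Counts of called list members come from the main model alone. The block called more genes in every comparison, so a member not called here may be called with it. A single slide holds 1 array per group and allows no test of its own, so values per slide are given without one.

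The steps were tested on simulated data with 200 changed genes. In the TGFβ1 comparison of siNC cells over 14486 genes, 43.7% of log2 changes of 0.5, 78.9% of changes of 1 and 98.3% of changes of 2 were recovered, with 7 false calls among 151. For the interaction with siFOXS1-1, 18.3%, 60.6% and 91.4% were recovered, with 2 false calls among 111. The simulated arrays had independent noise and no spread shared within slides, so these rates need not hold for the real arrays. Alternatives were quantile normalization, normexp background correction with an offset of 50, other filters on dim probes, the mean of a gene's probes, outlier spots kept, the replicate block, eBayes with a variance trend and robust settings, a 2-fold minimum, the authors' values, fits on only the groups compared, and each array and each slide left out. The normexp alternative used median spot intensities in place of the mean intensities first planned. A lower and a higher floor, unnamed transcripts kept, and the array with the highest background left out were added later. Matching of the siRNA seeds to transcript 3′ untranslated regions was planned but not run, because no transcript sequences were used here.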

Results

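Gene expression was measured in SNU-449 cells on 18 arrays, 3 for each combination of siRNA (siNC, siFOXS1-1 or siFOXS1-2) and treatment (BSA or TGFβ1). TGFβ1 is a cytokine that acts through SMAD transcription factors, and FOXS1 encodes a forkhead transcription factor. The series asks what loss of FOXS1 does to the transcripts of these cells with and without TGFβ1. Of the 50599 probes that are not controls, 46.5% to 56.2% were well above background on an array. The 75th percentile of the processed signal ranged from 394.9 to 522.7 units. Within a group, log2 differences between 2 arrays had a standard deviation of 0.22 to 0.48 across genes, and no pair of arrays held identical values. The array of siFOXS1-2 with TGFβ1 on slide 1 stood apart in its background, with a net signal of 69.1 units on the negative control probes. The other arrays of the FOXS1 siRNAs had 50.6 to 53.4 units and the siNC arrays 44.6 to 48.8.

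FOXS1 itself rose with TGFβ1 and fell with both siRNAs. In siNC cells its mean level was 0.01 ± 0.38 (SD, n = 3; log2 of the processed signal over the 75th percentile) with BSA and 3.36 ± 0.13 with TGFβ1, a 10.2-fold rise (log2 3.35 ± 0.38, adjusted p = 0.000120). With siFOXS1-1, FOXS1 fell to 11.1% of the siNC level in BSA (log2 -3.17, adjusted p = 2.31e-05) and by 3.47 on the log2 scale in TGFβ1 (adjusted p = 9.69e-06). With siFOXS1-2, FOXS1 was not above background on any of the 3 BSA arrays, at least 21.4-fold lower than in siNC cells (adjusted p = 1.88e-06), and in TGFβ1 it fell to 1.98% of the siNC level (log2 -5.66, adjusted p = 2.40e-07). Silenced cells still raised FOXS1 with TGFβ1, by 8.24-fold with siFOXS1-1 (log2 3.04, adjusted p = 0.000116) and by at least 4.31-fold with siFOXS1-2 (adjusted p = 0.00763). FOXS1 in siFOXS1-1 cells with TGFβ1 thereby stood at 91.7% of its level in untreated siNC cells, and in siFOXS1-2 cells at 20.2%. The first of these means rests on arrays that varied widely, at -1.24, 0.36 and 0.53 on slides 1 to 3 (SD 0.98). The siRNAs also differed from each other, with FOXS1 at least 2.38-fold higher with siFOXS1-1 in BSA (adjusted p = 0.0236) and higher by 2.19 on the log2 scale in TGFβ1 (adjusted p = 0.000733). The interactions, -0.30 for siFOXS1-1 and -1.18 for siFOXS1-2, did not pass the test (adjusted p = 1.00 for both). The siFOXS1-2 rise with TGFβ1 and the difference between the siRNAs in BSA rest on values at the floor, and both lost their calls with a higher floor (log2 1.16 and 0.31). The interaction with siFOXS1-2 rests on the same floored BSA arrays, so its -1.18 is no estimate of size and does not show a smaller rise of FOXS1. A single probe measured FOXS1.

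**Figure D1:**
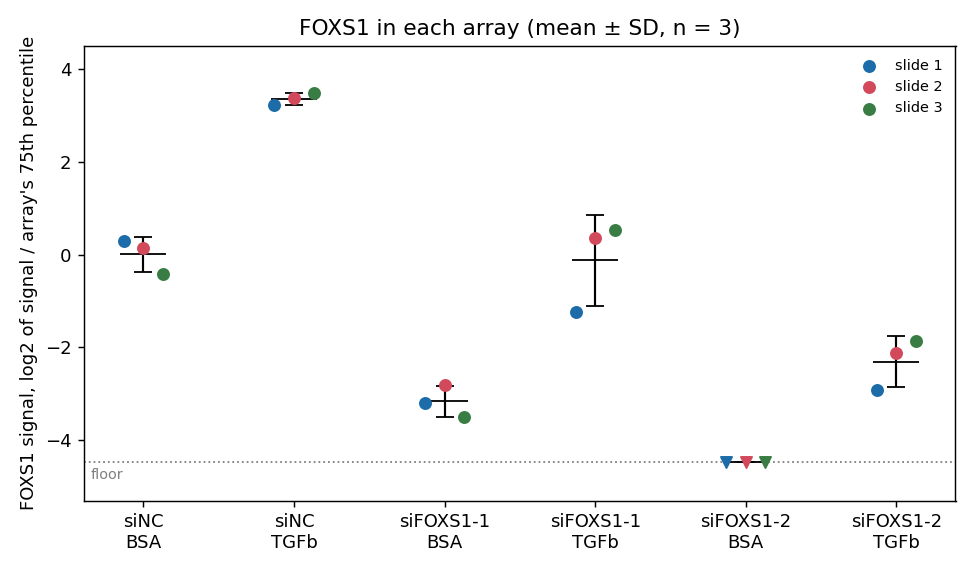
FOXS1 level on each of the 18 arrays (log2 of the processed signal divided by the array's 75th percentile), by siRNA and treatment, with colours for the 3 slides, black marks for the group mean ± SD, and a dotted line for the floor at -4.47, where triangles mark arrays set to it. TGFβ1 raised the group mean from 0.01 to 3.36 with siNC, and both FOXS1 siRNAs lie below siNC in either treatment.

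The first comparison asked what TGFβ1 changed in control cells after 72 h. In siNC cells TGFβ1 raised genes of TGFβ signalling and collagens, and other genes fell. Among the genes that met the conditions for naming, the largest rise was that of LRRC32, which encodes a membrane anchor of latent TGFβ (log2 3.81 ± 0.40), followed by the cytokine IL11 (3.62 ± 0.62) and the TGFβ family antagonist LEFTY1 (3.61 ± 0.20). The transcription factor MAF (3.43) rose too. NKAIN4 (3.40), the MyoD family inhibitor MDFI (2.98), the nucleotide receptor P2RY2 (2.90), the collagen chain COL1A1 (2.77 ± 0.29), the stromelysin MMP10 (2.54) and the chorionic gonadotropin subunit CGB3 (2.45) also rose, and the calcium pump regulator SLN rose at least 7.54-fold. Falls were those of the transcription factor HLF (log2 -2.33), the potassium channel KCNH5 (at least 3.98-fold lower), the phosphodiesterase PDE4B (-1.71), the activin subunit INHBB (-1.69), SMIM5 (-1.56) and RIPOR3 (-1.56). TLR3, a sensor of double-stranded RNA (-1.54), the interferon-induced IFIT2 (-1.48), VAC14-AS1 (-1.45), the serotonin receptor HTR2B (-1.45), the nuclear receptor NR0B1 (-1.34) and TMEFF2 (-1.31) fell as well. Among these 23 genes the adjusted p ran from 2.39e-07 (LEFTY1) to 0.0410 (VAC14-AS1). In the dimmer treatment HLF and VAC14-AS1 were above background on 1 of the 3 arrays and LRRC32, LEFTY1 and HTR2B on 2, so the floor affects their size (HLF ranged from -2.64 to -1.14 over the alternatives). Calls were lost in 12 of 22 alternatives for VAC14-AS1, 7 of 23 for RIPOR3, 6 of 23 for IFIT2, 6 of 22 for KCNH5, and at most 4 for each of the others. In all, 766 of 14486 genes were called, 442 higher and 324 lower, of which 155 changed at least 2-fold. The replicate block gave 3177 (1362 higher, 1815 lower) and kept every gene called without it. Fitted on its own 6 arrays the comparison called 313 genes, and with slide 2 left out 70.

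Of the 27 measured TGFβ and SMAD target genes, 17 rose and none fell (24 higher and 0 lower adjusted over the list alone), with a median log2 change of 0.84 (adjusted p = 1.65e-27, and adjusted p = 0.0119 with an estimated correlation). They included the matrix protein TGFBI (1.17), the latent TGFβ binding protein LTBP2 (1.65), and PMEPA1 (1.53) and SKIL (1.47), which restrain SMAD signalling. Of 34 ligands, receptors and regulators of the TGFβ family, 9 rose and 2 fell (14 and 4 adjusted over the list alone, median 0.29, adjusted p = 1.30e-06, and 0.00455 as the adjusted p with an estimated correlation). The activin antagonist FSTL3 (1.32) and the BMP receptor BMPR2 (1.17) were among those that rose. Of 17 collagens, 6 rose and none fell (7 and 1 adjusted over the list alone, median 0.30, adjusted p = 1.14e-06, and adjusted p = 0.0215 with an estimated correlation). They included COL5A1 (1.54), COL7A1 (1.35) and COL4A1 (0.76).

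The other list calls were lost with an estimated correlation. Contractile and smooth muscle genes had 6 of 21 higher and 1 lower (8 and 2 adjusted over the list alone, median 0.24, adjusted p = 3.64e-05, and adjusted p = 0.186 with an estimated correlation). TPM1 was at 0.70, TAGLN at 0.63 and ACTN1 at 0.37. Matrix proteases and inhibitors had 4 of 20 higher and 1 lower, over all genes and adjusted over the list alone (median 0.16, adjusted p = 0.00188, and adjusted p = 0.186 with an estimated correlation). ADAM19 was at 1.47 and ADAMTS6 at 1.28. Mesenchymal markers had 2 of 11 higher, FAP (2.27) and N-cadherin CDH2 (0.93), and 4 higher and 1 lower adjusted over the list alone (median 0.20, adjusted p = 0.0103, and adjusted p = 0.0728 with an estimated correlation). The fibronectin gene FN1, at 1.16, missed the call (adjusted p = 0.0550). Integrins had 2 of 16 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.18, adjusted p = 0.0145, and adjusted p = 0.473 with an estimated correlation). ITGAV was at 0.76, ITGB6 at 1.08 and ITGA6 at -0.45. Transcription factors of epithelial-mesenchymal transition had FOXS1 and SNAI1 (2.45) higher and TWIST1 (-0.60) lower of 12 (5 and 2 adjusted over the list alone, median 0.34, adjusted p = 0.0320, and adjusted p = 0.382 with an estimated correlation), a list call that the replicate block lost (adjusted p = 0.0801). With only spots above background on all 18 arrays kept, which removes FOXS1, the list mean minus other genes was 0.23 (adjusted p = 0.844). The ID genes, inhibitors of helix-loop-helix factors, had ID3 (1.00) and ID2 (0.38) higher of 4, over all genes and adjusted over the list alone (median 0.10, adjusted p = 0.0415, and adjusted p = 0.186 with an estimated correlation), also lost in the block (adjusted p = 0.169). Hedgehog and notch pathway genes had GLI2 (0.62) and JAG1 (0.74) higher of 17 by either adjustment, adjusted over the list alone included (median 0.07, adjusted p = 0.0415, and adjusted p = 0.186 with an estimated correlation). Cholesterol synthesis genes had SQLE (0.36) and SC5D (0.78) higher of 24 (3 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.00188, and adjusted p = 0.623 with an estimated correlation). That call was also lost without siNC array 3 with BSA (list mean minus other genes 0.081, adjusted p = 0.0967) or siNC array 1 with TGFβ1 (0.088, adjusted p = 0.0976).

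Interferon-stimulated genes had 0 of 30 higher and 3 lower (0 and 6 adjusted over the list alone, median -0.32, adjusted p = 0.000217, and adjusted p = 0.473 with an estimated correlation). The 3 were IFIT2, OAS3 (-0.63) and IFIT5 (-0.39). Inflammatory and NF-κB target genes had IL11 higher and NFKBIA (-0.32) and ICAM1 (-0.56) lower of 21 (1 and 4 adjusted over the list alone, median -0.34, adjusted p = 0.0167, and adjusted p = 0.473 with an estimated correlation). This list lost its call in 5 of 23 alternatives. Without siNC array 1 with TGFβ1 its mean minus other genes was -0.016 (adjusted p = 0.320). NRF2 target genes had ABCC2 (-1.11), OSGIN1 (-0.61) and the glutathione synthesis gene GCLC (-0.35) lower of 20, over all genes and adjusted over the list alone (median -0.20, adjusted p = 0.0104, and adjusted p = 0.473 with an estimated correlation). The 32 DNA replication and G1/S genes (median -0.14, adjusted p = 0.000757, and adjusted p = 0.481 with an estimated correlation) and the 33 G2/M and mitosis genes (median -0.11, adjusted p = 0.0103, and adjusted p = 0.611 with an estimated correlation) had no called member, over all genes or adjusted over the list alone.

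The remaining lists were not called with TGFβ1 in siNC cells. Epithelial markers had KRT7 (0.52) higher and CLDN1 (-0.47) lower of 19 (2 and 2 adjusted over the list alone, as are all such pairs in this paragraph), matrix glycoproteins, proteoglycans and crosslinkers had LOXL4 (0.92) and EFEMP1 (0.63) higher and LAMA4 (-0.78) lower of 28 (4 and 3), and YAP and TAZ target genes had CCN2 (1.51) and F3 (0.39) among 2 higher and FJX1 (-0.75) and AMOTL2 (-0.43) among 4 lower of 19 (3 and 5). Hepatocyte genes had the fibrinogen gene FGG (-1.18) lower of 16 (0 and 1), liver progenitor and stemness genes ICAM1 lower of 16 (0 and 2), and p53 target genes TP53I3 (0.82) higher of 22 (2 and 1). Hypoxia and glycolysis genes had SLC2A1 (0.69) and PFKFB3 (0.37) higher and ADM (-0.72) lower of 22 (2 and 2). Integrated stress response and unfolded protein response genes had MANF (0.38) higher and CEBPB (-0.62) lower of 28 (2 and 1), and autophagy and lysosome genes had ULK1 (1.76) and WIPI1 (0.44) higher of 21 (2 and 1). Forkhead family genes had FOXS1 and FOXP1 (0.38) higher of 29 (2 and 0), and the 4 endothelial markers had ROBO4 (0.88) higher (1 and 0). Leukocyte markers (8 measured; 0 and 1), fatty acid synthesis genes (17; 0 and 0) and siRNA machinery genes (13; 0 and 0) had no called member over all genes.

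The same comparison was made in FOXS1-silenced cells, and many of the genes called in siNC cells were called there too. With siFOXS1-1 large rises included those of IL11 (log2 4.51), LRRC32 (4.02) and SLN (at least 16.2-fold), and falls included those of INHBB (-2.81), HLF (-2.71), the secreted protein AGR2 (-2.37), the cytokine IL1B (-2.21) and the interferon-induced MX1 (-2.16). HLF, AGR2 and IL1B were above background on 1 of 3 arrays with TGFβ1 there, so the floor affects their size. With siFOXS1-2 large rises included NKAIN4 (3.23), IL11 (3.20), COL1A1 (2.80) and FAP (2.07), and falls included INHBB (-1.48), RIPOR3 (-1.37), SMIM5 (-1.21), NPTX1 (-1.08) and PLPP3 (-1.06). Of 23 alternatives for siFOXS1-2, calls were lost in 12 for RIPOR3, 10 for NPTX1, 7 for SMIM5 and IL11, 6 for INHBB and FAP, 4 for PLPP3 and 2 for COL1A1. Of the 442 genes higher in siNC cells, 389 were also called higher with siFOXS1-1 and 195 with siFOXS1-2, where independent lists would share 26.1 and 6.50. Of the 324 lower genes, 258 and 105 were also called lower (20.5 and 2.89 for independent lists), and none was called in the opposite direction. Across genes, which are not independent replicates, the log2 changes correlated with those of siNC cells at 0.829 with siFOXS1-1 and 0.774 with siFOXS1-2. In total 1770 genes were called with siFOXS1-1 (854 higher, 916 lower; 4870 with the replicate block, 2026 and 2844) and 342 with siFOXS1-2 (213 higher, 129 lower; 2512 with the block, 972 and 1540). Fitted on their own arrays these were 869 and 10, and with slide 2 left out 332 and 35.

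TGFβ and SMAD target genes were called as a list with either siRNA, 22 of 27 higher with siFOXS1-1 (also 22 adjusted over the list alone, median 1.03, adjusted p = 1.16e-23, and adjusted p = 0.0212 with an estimated correlation) and 8 of 27 with siFOXS1-2 (19 adjusted over the list alone, median 0.61, adjusted p = 2.24e-23, and adjusted p = 0.0222 with an estimated correlation). Collagens were called in both, with 7 and 4 of 17 higher and none lower (7 in each, adjusted over the list alone, medians 0.28 and 0.20, adjusted p = 0.0249 and 0.0222 with an estimated correlation). So were regulators of the TGFβ family, with 14 and 3 of 34 higher and 2 lower in each (16 and 6 higher, 2 and 3 lower, adjusted over the list alone, adjusted p = 0.00612 and 0.0276 with an estimated correlation). In siFOXS1-1 cells 10 of 30 interferon-stimulated genes fell and 1 rose (15 and 1 adjusted over the list alone, median -0.40, adjusted p = 0.000265, and adjusted p = 0.478 with an estimated correlation), and 9 of 32 DNA replication genes fell (11 adjusted over the list alone, median -0.15, adjusted p = 4.89e-05, and adjusted p = 0.464 with an estimated correlation). In siFOXS1-2 cells neither list had more than 1 called member.

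**Figure D2:**
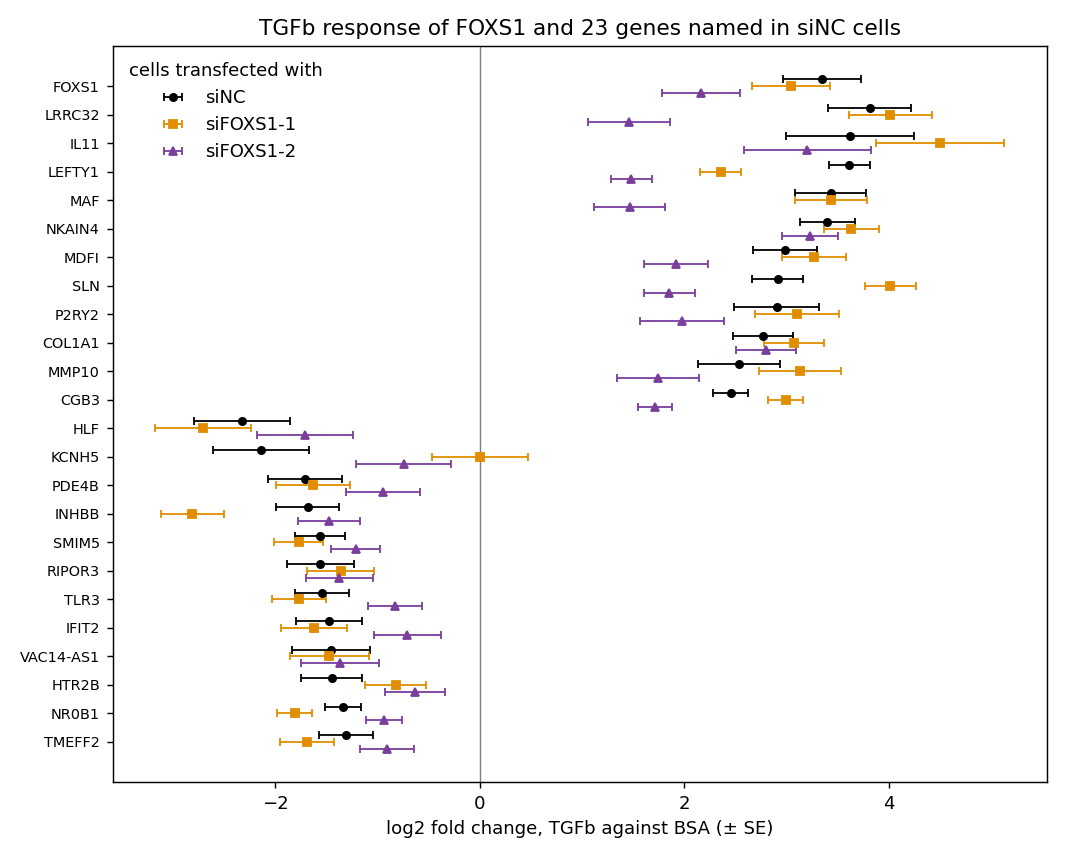
Log2 change with TGFβ1 against BSA (points, with lines for ± SE from the model) of FOXS1 and 23 genes among those with the largest changes in siNC cells, for siNC, siFOXS1-1 and siFOXS1-2 (3 arrays per group). The genes keep their sign with all 3 siRNAs except KCNH5, which lies at the floor in both treatments with siFOXS1-1, and the point is no estimate of the size where a group had no array above background (SLN and KCNH5 with all 3 siRNAs, MMP10 with siFOXS1-1, FOXS1 and LRRC32 with siFOXS1-2, HTR2B with both FOXS1 siRNAs).

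The next comparisons asked which genes changed when FOXS1 was silenced. Both siRNAs changed many genes in each treatment, and a large group moved the same way with both. In BSA the largest shared rises among genes that met the conditions for naming, given for siFOXS1-1 and then siFOXS1-2, were those of the U1 splicing factor SNRPC (log2 2.15 and 2.15), the ubiquitin-conjugating enzyme variant UBE2V1 (2.28 and 2.09), the ER membrane complex subunit EMC10 (2.08 and 1.99), the retinol dehydrogenase RDH11 (1.97 and 1.84), the phosphomannomutase PMM2 (1.83 and 2.02), the Wnt receptor FZD5 (2.47 and 1.82), COMMD10 (2.21 and 1.81) and PGM2L1 (1.94 and 1.80), each ± 0.09 to 0.14. Apart from FOXS1, the largest shared falls among such genes were those of the spectrin SPTB (-1.94 and -1.86), the 14-3-3 protein SFN (-1.79 with siFOXS1-2), EMP1 (at least 3.78-fold lower and -1.60), the sialic acid receptor CD33 (-2.14 and -1.50), the gelatinase MMP9 (-1.62 and -1.46), TBC1D2 (-1.58 and -1.42), CXXC5 (-1.32 and -1.44) and thrombomodulin, THBD (-1.32 and -1.84). In TGFβ1 the same rule named SNRPC (2.16 and 2.11), UBE2V1 (2.30 and 2.04), EMC10 (1.96 and 1.91), FZD5 (2.62 and 1.82) and PMM2 (1.79 and 1.86) again, with the kinase inhibitor PKIA (2.16 and 2.05), the copper transporter SLC31A1 (1.80 and 1.84) and RP2 (1.92 and 1.75). Falls shared in TGFβ1, apart from that of FOXS1, were those of SFN (-2.06 and -1.93), the FGF-binding protein FGFBP1 (-1.88 and -2.35), the amylase AMY1C (-1.90 and -1.77), SPTB (-1.58 and -1.91), THBD (-1.54 and -2.02), CD33 (-2.12 and -1.46), the forkhead gene FOXI1 (-1.46 and -1.59) and EMP1 (at least 3.95-fold lower and -1.43). CXXC5 lost its call in 8 of 22 alternatives with siFOXS1-1 and 9 of 22 with siFOXS1-2, with values as small as -0.62. Each of the other shared genes lost it in at most 3.

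In BSA siFOXS1-1 changed 4675 genes (2827 higher, 1848 lower; 8060 with the replicate block, 4583 and 3477) and siFOXS1-2 changed 3170 (1824 higher, 1346 lower; 6748 with the block, 3658 and 3090). Of these, 467 and 251 changed at least 2-fold. Both siRNAs raised 1255 genes and lowered 611, where independent lists would share 356.0 and 171.7, and 138 genes were called in opposite directions. In TGFβ1 the counts were 4883 (2911 higher, 1972 lower; 8324 with the block, 4636 and 3688) and 3324 (1853 higher, 1471 lower; 7084 with the block, 3790 and 3294), with 566 and 276 changed at least 2-fold. There both raised 1208 and lowered 617 (372.4 and 200.2 for independent lists), with 192 opposite. The siRNAs are compared with the same siNC arrays, so part of the excess may come from those. Simulated unchanged groups, which give no calls, cannot measure that part (0 shared). Across genes, the changes with the siRNAs correlated at 0.590 in BSA and 0.504 in TGFβ1 (simulated 0.50 and 0.496). Covariances were 0.0902 and 0.0860 (simulated 0.0200 and 0.0198). Comparisons without an array in common, siFOXS1-1 in BSA with siFOXS1-2 in TGFβ1 and the reverse, shared 1834 and 1802 genes and correlated at 0.510 and 0.525. The first pairing shared 1218 higher and 616 lower genes (361.6 and 187.7 for independent lists). The reverse pairing shared 1230 and 572 (366.5 and 183.2 for independent lists). The same siRNA in the other treatment shared 3832 genes for siFOXS1-1 (4 opposite) and 2652 for siFOXS1-2 (0 opposite).

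**Figure D3:**
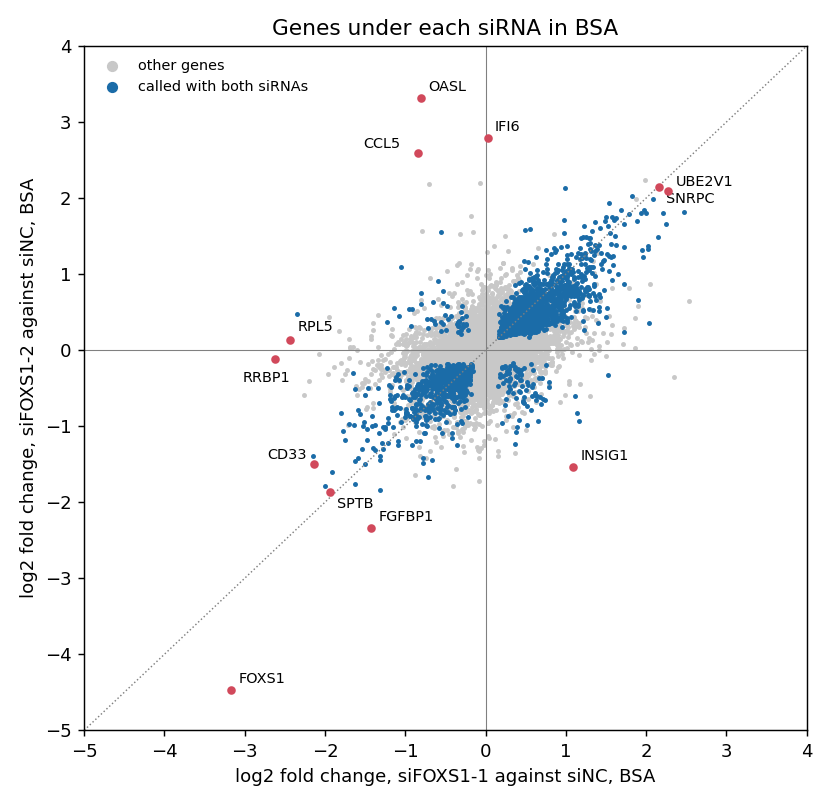
Log2 change with siFOXS1-1 (x axis) and with siFOXS1-2 (y axis) against siNC in BSA, 1 point per gene, with genes called with both siRNAs, in the same or in opposite directions, in blue and 12 genes labelled in red. SNRPC, UBE2V1 and SPTB lie near the diagonal, OASL (3.31) and CCL5 (2.59) are high with siFOXS1-2, RPL5 (-2.43) and RRBP1 (-2.62) are low with siFOXS1-1, and the value of FOXS1 with siFOXS1-2 rests on the floor.

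Beyond the shared genes, siFOXS1-1 raised some cell division and cholesterol genes. Of 33 G2/M and mitosis genes, 23 rose and 1 fell in BSA (24 and 1 adjusted over the list alone, median 0.36, adjusted p = 6.08e-06, and adjusted p = 0.953 with an estimated correlation). The spindle genes HMMR (0.92) and NDC80 (0.77), cyclin A, CCNA2 (0.76), and the checkpoint kinase BUB1 (0.56) were among them. In TGFβ1 23 rose and none fell, also adjusted over the list alone (median 0.36, adjusted p = 3.41e-06, and adjusted p = 0.849 with an estimated correlation). Of 24 cholesterol synthesis genes, 13 rose and none fell in BSA (14 and 0 adjusted over the list alone, median 0.61, adjusted p = 0.000192, and adjusted p = 0.953 with an estimated correlation). IDI1 was at 1.26, HMGCS1 at 1.00 and CYP51A1 at 0.76. In TGFβ1 14 rose, also adjusted over the list alone (median 0.46, adjusted p = 0.000856, and adjusted p = 0.849 with an estimated correlation). Among genes that met the conditions for naming, those raised most by siFOXS1-1 were FZD5, UBE2V1, COMMD10, SNRPC and the nucleoporin NUP35 (2.25) in BSA, and the homeobox gene PRRX2 (2.68), FZD5, RASGRP3 (2.37), UBE2V1 and NUP35 (2.26) in TGFβ1. Apart from FOXS1, those lowered most in BSA were the ribosome receptor RRBP1 (-2.62), the ribosomal protein gene RPL5 (-2.43), the sorting nexin SNX10 (-2.27), INAVA (-2.19) and KCNH5 (at least 4.42-fold lower). In TGFβ1, again apart from FOXS1, they were SNX10 (-2.58), RRBP1 (-2.47), RPL5 (-2.43), the kinase SBK1 (-2.41) and RAB17 (at least 4.02-fold lower). Some lists were called for siFOXS1-1 only with the replicate block, namely fatty acid synthesis genes (adjusted p = 0.205 without it and 0.0469 with it in BSA, 0.13 and 0.0286 in TGFβ1) and, in TGFβ1, epithelial markers (0.135 and 0.0459) and DNA replication genes (0.0612 and 0.0319).

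With siFOXS1-2 some interferon-stimulated genes rose. In BSA 13 of 30 interferon-stimulated genes rose and none fell (14 and 0 adjusted over the list alone, median 0.44, adjusted p = 0.000157, and adjusted p = 0.921 with an estimated correlation). With only spots above background on all 18 arrays kept, the list lost its call (list mean minus other genes 0.54, adjusted p = 0.0687). OASL was at 3.31 ± 0.35 (1.81 to 3.77 over the alternatives), OAS3 at 1.58 and HERC5 at 1.56. RSAD2 was at 2.19, but siNC cells had it above background on 1 of 3 arrays, so the floor sets its size (0.95 to 2.96 over the alternatives). In TGFβ1 14 rose and none fell (17 and 0 adjusted over the list alone, median 0.70, adjusted p = 2.19e-06, and adjusted p = 0.804 with an estimated correlation). OASL was at 3.45, OAS3 at 1.98, HERC5 at 1.81 (above background on 1 of 3 siNC arrays) and RSAD2 at least 3.84-fold higher. Among genes that met the conditions for naming, those raised most in BSA were OASL, the interferon-induced IFI6 (2.79), the chemokine CCL5 (2.59), RSAD2 and the chemokine CCL3 (2.18), and in TGFβ1 OASL, IFI6 (2.98), CCL5 (2.65), LST1 (2.30) and DDAH1 (2.13). Apart from FOXS1, those lowered most in BSA were FGFBP1 (-2.34), SPTB, THBD, SFN and the glycosyltransferase GALNT1 (-1.79). In TGFβ1, again apart from FOXS1, they were LRRC32 (-2.68), LEFTY1 (-2.40), FGFBP1 (-2.35), MAF (-2.28) and the succinate receptor SUCNR1 (-2.18), of which LRRC32, LEFTY1 and MAF were among the genes that TGFβ1 raised most in siNC cells. Of 27 TGFβ and SMAD target genes, 5 were lower than in siNC cells with TGFβ1 and none higher, also adjusted over the list alone (median -0.35, adjusted p = 0.0198, and adjusted p = 0.970 with an estimated correlation). LTBP2 was at -0.89, TGFB1 at -0.69, PMEPA1 at -0.57 and LTBP3 at -0.52. This list lost its call without siNC array 3 (list mean minus other genes -0.23 against -0.30, adjusted p = 0.0920) and without siFOXS1-2 array 1, the one with the raised background (-0.13, adjusted p = 0.141), both with TGFβ1. NRF2 target genes were called in TGFβ1 only with the block (adjusted p = 0.124 without it and 0.0314 with it).

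The siRNAs were then compared directly, which tests where they differed. In BSA 3181 genes differed (1869 higher with siFOXS1-1, 1312 lower; 6831 with the replicate block, 3769 and 3062) and in TGFβ1 3961 (2255 higher, 1706 lower; 7581 with the block, 4051 and 3530). Of genes called with siFOXS1-1 alone, this test called 1496 of 2671 in BSA and 1784 of 2866 in TGFβ1; for siFOXS1-2 it called 667 of 1166 and 806 of 1307. In BSA the sterol sensor partner INSIG1 (2.63), the splicing factor PTBP3 (2.10), PTPRD (1.96) and the ubiquitin ligase MYLIP (1.90) were higher with siFOXS1-1, and OASL (at least 17.4-fold), CCL5 (-3.43), CCL3 (-2.88) and IFI6 (-2.76) were lower. In TGFβ1 PRRX2 (3.30), LRRC32 (2.84), INSIG1 (2.77) and SSC5D (2.45) were higher, and OASL (at least 14.9-fold), MX1 (-3.80), CCL5 (-3.41) and IFI6 (-2.98) lower. Of 30 interferon-stimulated genes, those lower with siFOXS1-1 numbered 13 in BSA (14 lower and 1 higher adjusted over the list alone, median -0.53, adjusted p = 5.56e-09, and adjusted p = 0.786 with an estimated correlation) and 20 in TGFβ1 with 1 higher, by either adjustment (median -0.99, adjusted p = 8.48e-11, and adjusted p = 0.547 with an estimated correlation).

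Of 33 G2/M genes, 23 in BSA and 24 in TGFβ1 were higher with siFOXS1-1, with 1 lower in each (26 and 27 higher adjusted over the list alone, median 0.36 in each, adjusted p = 4.47e-10 and 3.22e-09, and adjusted p = 0.742 and 0.547 with an estimated correlation). Of 24 cholesterol synthesis genes, 12 in BSA and 13 in TGFβ1 were higher (14 in each adjusted over the list alone, medians 0.41 and 0.52, adjusted p = 8.25e-05 and 3.27e-05, and adjusted p = 0.984 and 0.639 with an estimated correlation). In TGFβ1 alone, 14 of 27 TGFβ and SMAD target genes were higher with siFOXS1-1 and 1 lower (15 and 1 adjusted over the list alone, median 0.56, adjusted p = 3.02e-05, and adjusted p = 0.565 with an estimated correlation). Inflammatory and NF-κB target genes had 5 of 21 lower there, also adjusted over the list alone (median -0.50, adjusted p = 0.0109, and adjusted p = 0.639 with an estimated correlation). NRF2 target genes had 7 of 20 lower and 1 higher there (8 and 1 adjusted over the list alone, median -0.25, adjusted p = 0.0278, and adjusted p = 0.639 with an estimated correlation). Fatty acid synthesis genes were called only with the block in BSA (adjusted p = 0.206 without it and 0.0373 with it) and TGFβ1 (0.123 and 0.0309), as were collagens (0.0512 and 0.0352) and contractile genes (0.127 and 0.0376) in TGFβ1.

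**Figure D4:**
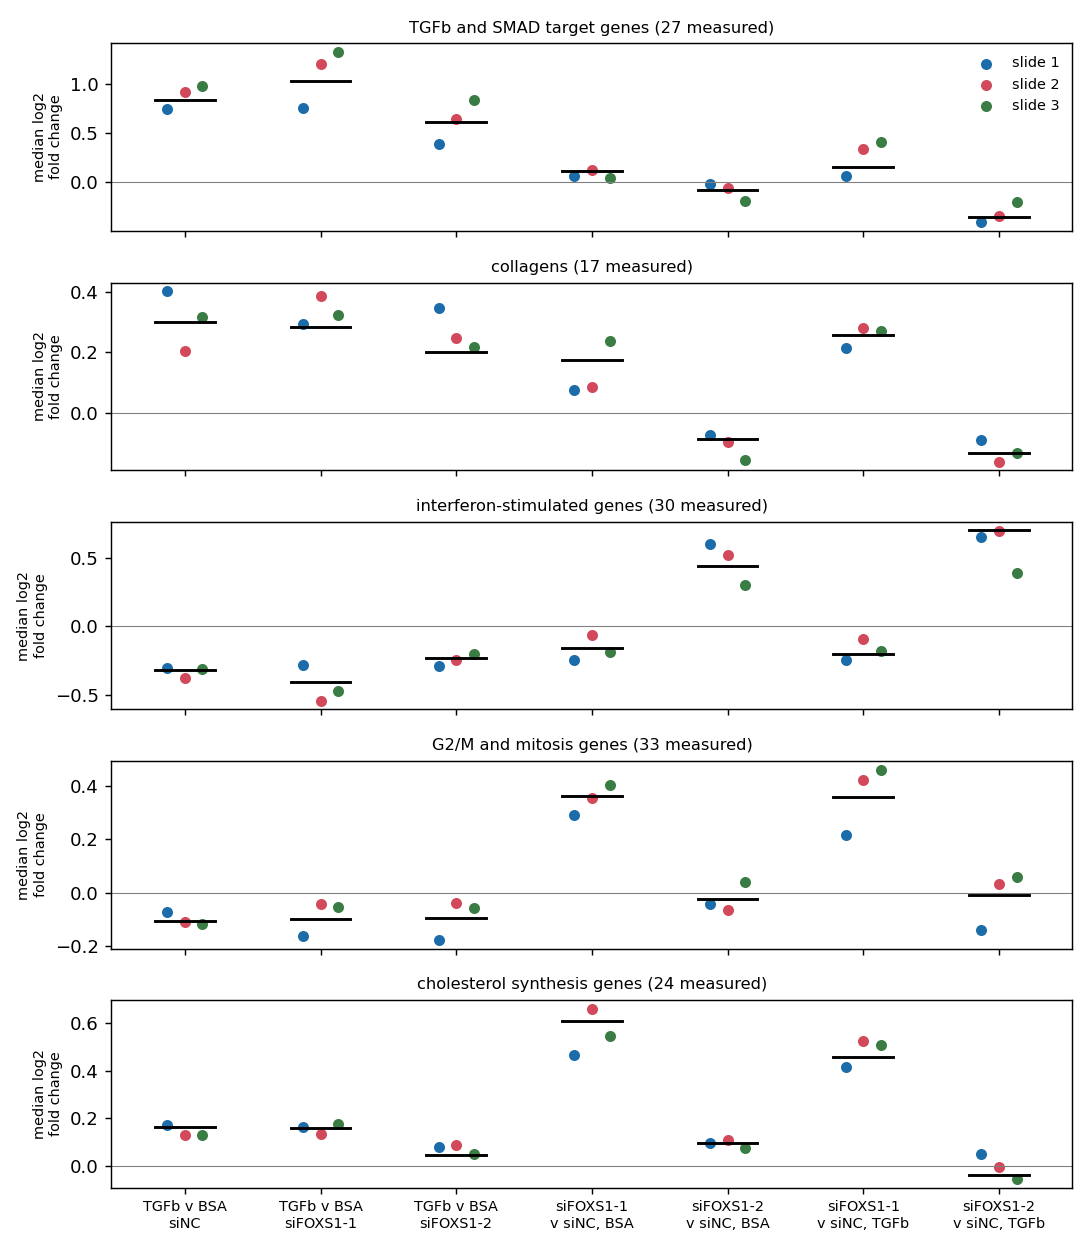
Median log2 change of 5 gene lists (27 TGFβ and SMAD targets, 17 collagens, 30 interferon-stimulated, 33 G2/M and 24 cholesterol synthesis genes) in 7 comparisons, with the median over all arrays as a bar and the median on each of the 3 slides as points. Target genes and collagens are above 0 with TGFβ1 under all 3 siRNAs, interferon-stimulated genes are above 0 with siFOXS1-2 alone (0.44 and 0.70), and G2/M and cholesterol genes have their highest medians with siFOXS1-1 (0.36 and 0.61 in BSA).

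The last comparison asked whether the response to TGFβ1 itself differed when FOXS1 was silenced, and few single genes passed this test. With siFOXS1-1, 9 of 14486 genes had a different response (interaction above 0 in 7 and below 0 in 2; 64 with the replicate block, 40 and 24; 398 at an unadjusted p below 0.05). NXPH4 (1.21), PARP8 (0.78), the receptor adaptor GRB10 (0.74) and MBOAT2 (0.64) rose more with TGFβ1 than in siNC cells. These calls were lost in 16, 22, 21 and 19 of 29 alternatives. The other 5 genes had groups at the floor, which sets the size of their difference. LDLRAD4, an inhibitor of SMAD signalling, was above background on all 3 arrays only in siFOXS1-1 cells with TGFβ1, where it was at least 5.61-fold higher than with BSA. In siFOXS1-1 cells with TGFβ1 the serine palmitoyltransferase subunit SPTLC3 and CFAP276 were on no array above background, at least 2.43-fold and 1.48-fold lower than with BSA. LDLRAD4 lost its call in 20 of 28 alternatives, CFAP276 in 16 and SPTLC3 in 7. With siFOXS1-2, 3 genes passed (2 and 1; 4 with the block, 3 and 1; 174 at an unadjusted p below 0.05). LEFTY1 had a response smaller by 2.13 on the log2 scale, which is to say 1.48 in siFOXS1-2 cells against 3.61 in siNC cells, with BSA arrays partly below background in both. Its call was lost in 14 of 28. MST1R, a receptor tyrosine kinase, and USP3-AS1 passed with both siRNAs and were above background on all 3 arrays only in siNC cells with BSA, at least 2.31-fold and 1.37-fold higher than in siNC cells with TGFβ1. A fall could not be seen with the FOXS1 siRNAs. The call of MST1R was lost in 7 and 9 of 28 alternatives and that of USP3-AS1 with siFOXS1-2 in 10. With the authors' values the signs of LDLRAD4 (-0.43) and MST1R with siFOXS1-1 (-0.16) were reversed and neither interaction called a gene.

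Over all genes that responded on average to TGFβ1, the response was larger with siFOXS1-1 than with siNC and not called different with siFOXS1-2. For siFOXS1-1 the median difference over 2720 genes was 0.11 in the direction of the response (adjusted p = 0.0369 by limma's fry over the 2 siRNAs), and 22.8% of the genes had a smaller response. The slides gave 0.04, 0.14 and 0.16, and the block gave 0.07 over 6208 genes (adjusted p = 0.0132). At an unadjusted p below 0.05 this test was passed with all arrays and failed without siNC array 3 with BSA, siNC array 1 or 2 with TGFβ1, slide 2 or slide 3. For siFOXS1-2 it was -0.07 over 1657 genes (adjusted p = 0.0959), with 71.4% smaller. The slides gave -0.09, -0.10 and -0.02, and the block gave -0.03 over 5258 genes (adjusted p = 0.202). The response of TGFβ and SMAD target genes was larger with siFOXS1-1 (median 0.14, adjusted p = 0.0125, and adjusted p = 0.811 with an estimated correlation), and smaller with siFOXS1-2 (median -0.24, adjusted p = 5.38e-06, and adjusted p = 0.428 with an estimated correlation). Without the siFOXS1-2 array with the raised background that median was -0.023 in the fit without the replicate number, and the list lost its call (adjusted p = 0.0788). Within the slides that do not hold that array, the medians were -0.26 and -0.016. The call was kept in 27 of 29 alternatives, among them the fit without all of slide 1, which holds that array. The 2 losses were both the fit without that array alone. For siFOXS1-1 the call was lost without siNC array 1 (adjusted p = 0.128), siFOXS1-1 array 2 or 3 (adjusted p = 0.111 and 0.390) with TGFβ1, siFOXS1-1 array 3 with BSA (adjusted p = 0.0595), slide 2 (adjusted p = 0.0949) or slide 3 (adjusted p = 0.433). No member passed the test by itself, over all genes or adjusted over the list alone. For TGFβ family regulators the interaction with siFOXS1-2 was below 0 (median -0.13, adjusted p = 5.38e-06, and adjusted p = 0.00564 with an estimated correlation; 1 of 34 lower, LEFTY1, and 2 adjusted over the list alone). This call was kept in all 29 alternatives, with a list mean minus other genes of -0.32 that moved to -0.115 with the filter for spots above background on all 18 arrays.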

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

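The tests of the 3 patterns weighed here were chosen only after the results were seen, while the tests of differences between siRNAs and the counts over other splits of the arrays were planned.

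The first pattern is the group of 1476 genes that both FOXS1 siRNAs changed in the same direction under both treatments (1035 higher, 441 lower; median change 0.57). Chance values of the shared siNC arrays were argued against, since the 2 pairings of comparisons without an array in common still shared 1834 and 1802 genes, the latter 3.28 times the number from independent lists. The change with TGFβ1 minus that with BSA was -1.42% of the median change over all slides (-11.5%, 3.11% and 3.05% on the single slides), but these genes had to be called in both treatments, which favours a difference near 0. That value therefore decides neither for nor against an effect of the control siRNA or an effect of FOXS1 loss that grows with the FOXS1 level, which both remain candidate explanations. A loss of FOXS1 whose effect does not depend on its level also stays open, untested. The siNC arrays also held their own positions on the slides and had the lowest negative control signals, which cannot be told apart from the siRNA.

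The second pattern is the higher level of interferon-stimulated genes with siFOXS1-2 than with siFOXS1-1 (median difference -0.99 in TGFβ1, siFOXS1-1 minus siFOXS1-2). Loss of FOXS1 to the depth reached with siFOXS1-1 was argued against as the whole cause. With that siRNA the list median in TGFβ1 had a mean over slides of -0.17 (-0.25, -0.09 and -0.18 on the slides). Within a treatment FOXS1 was lower still with siFOXS1-2, so these values do not decide about a deeper loss relative to siNC. Between treatments, mean FOXS1 was at 20.2% of the untreated siNC level with siFOXS1-2 in TGFβ1 and at 11.1% with siFOXS1-1 in BSA, with overlapping arrays. The list medians against siNC of the same treatment were 0.70 and -0.15 there. Those values argue against an effect set by the FOXS1 level reached alone, for those groups. The array with the raised background was argued against as well, because the slides that do not hold it gave -1.09 and -0.91. An off-target or innate immune effect of the siFOXS1-2 duplex, and a graded effect of its deeper loss of FOXS1 relative to siNC, may both apply and were not tested. The planned matching of siRNA seeds to transcripts, which bears on the first of these, was not run.

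The third pattern is a smaller TGFβ1 response of TGFβ target genes with siFOXS1-2 and a larger response with siFOXS1-1. Over TGFβ1-responsive genes the median difference from siNC was 0.11 with siFOXS1-1 and -0.07 with siFOXS1-2, with those signs on every slide. The siFOXS1-2 difference was not called (adjusted p = 0.0959 by fry). That of siFOXS1-1 failed its test in 5 of 15 fits with an array or slide left out. Opposite signs were part of the pattern as chosen, so they do not decide whether loss of FOXS1 was the whole cause. For the target list the part played by the array with the raised background is only partly settled. The median difference was -0.41 on the slide that holds it, and -0.26 and -0.016 on the others. It was -0.023 over all groups when that array alone was left out, a fit in which the groups no longer cover the same slides. The list lost its call in that fit and kept it without all of slide 1, so the call did not need that array. The unlike medians of the other slides leave the size of the difference open. A graded effect of FOXS1 loss, deeper with siFOXS1-2, could fit the direction in siFOXS1-2 cells and leaves the larger response with siFOXS1-1 without an explanation, and was not tested.

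Differences between siRNA groups in the response to TGFβ1 were picked out by the interaction test. The values of LDLRAD4, SPTLC3, MST1R, CFAP276 and USP3-AS1 rest on groups at the floor and are no estimates of size. With siFOXS1-1 these were LDLRAD4 (2.15), SPTLC3 (-1.50), MST1R (1.27), NXPH4 (1.21), PARP8 (0.78), CFAP276 (-0.76), GRB10 (0.74), MBOAT2 (0.64) and USP3-AS1 (0.61), and with siFOXS1-2 they were LEFTY1 (-2.13), MST1R (1.21) and USP3-AS1 (0.61). The median response over TGFβ1-responsive genes was larger by 0.11 with siFOXS1-1.

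For gene lists the difference is given as the list mean minus that of all other genes. With siFOXS1-1 it was 0.20 for TGFβ and SMAD target genes (adjusted p = 0.0125, and adjusted p = 0.811 with an estimated correlation), -0.30 for epithelial markers (adjusted p = 0.0315, and adjusted p = 0.811 with an estimated correlation) and 0.15 for collagens (adjusted p = 0.0125, and adjusted p = 0.776 with an estimated correlation). With siFOXS1-2 it was -0.26 for target genes (adjusted p = 5.38e-06, and adjusted p = 0.428 with an estimated correlation), -0.33 for ID genes (adjusted p = 0.00314, and adjusted p = 0.0608 with an estimated correlation) and -0.34 for transcription factors of epithelial-mesenchymal transition (adjusted p = 0.0191, 0.136 with the replicate block, and adjusted p = 0.428 with an estimated correlation). It was 0.15 for interferon-stimulated genes (adjusted p = 0.0206, and adjusted p = 0.958 with an estimated correlation), 0.11 for inflammatory and NF-κB targets (adjusted p = 0.0191, and adjusted p = 0.757 with an estimated correlation), -0.10 for cholesterol synthesis genes (adjusted p = 0.0385, and adjusted p = 0.958 with an estimated correlation) and -0.32 for regulators of the TGFβ family (adjusted p = 5.38e-06, and adjusted p = 0.00564 with an estimated correlation). With 1 array left out the sign turned for interferon-stimulated genes (-0.034), NF-κB targets (-0.051 and -0.034) and cholesterol synthesis genes (0.0014 and 0.00073). The list of transcription factors includes FOXS1 itself. With only spots above background on all 18 arrays kept, which removes FOXS1, that list was at -0.126 (adjusted p = 0.779). Of 29 alternatives, calls were lost in 13 for epithelial markers (-0.17 with the authors' values, adjusted p = 0.139) and 12 for transcription factors. They were lost in 12 for interferon-stimulated genes, 9 for cholesterol synthesis genes, 8 for NF-κB targets and at most 6 for each other list.

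Outside the named genes, transcripts whose accessions matched no symbol also changed. Of 7051 such probes, 160 were called with TGFβ1 in siNC cells, 1071 with siFOXS1-1 and 593 with siFOXS1-2 in BSA, and 1110 and 661 in TGFβ1.

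Other splits of the arrays were counted for each number of called genes. With 3 arrays against 3 there are 10 splits, too few for a share below 0.05, and only 1, the real one, gave as many genes in each of the 9 pairwise comparisons. Every other split puts arrays of both groups on each side, so a real difference adds to the spread and lowers the count. The counts of those splits are therefore no measure of what chance gives. The real count and the highest of the other splits were 766 and 2 for TGFβ1 in siNC cells, 1770 and 0 in siFOXS1-1 cells, and 342 and 0 in siFOXS1-2 cells. They were 4675 and 0 for siFOXS1-1 and 3170 and 0 for siFOXS1-2 in BSA, 4883 and 2 and 3324 and 3 in TGFβ1, and 3181 and 0 in BSA and 3961 and 2 in TGFβ1 for the siRNAs against each other. Since the replicate numbers pair the samples, the real split was also set against those that part as many pairs, which gave at most 0, or 1 for the siRNAs against each other in TGFβ1; the others keep pairs on 1 side. For the interactions, 5 of 100 assignments of the arrays gave at least the 9 genes of siFOXS1-1 and 11 of 100 the 3 genes of siFOXS1-2, but this is no measure of what chance gives for an interaction. Those assignments called up to 2229 and 1385 genes, many times the real counts, which points to a structure of the samples, since they mix the differences between siRNAs and treatments into the interaction and ignore the slides.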

How the results depend on the processing

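The lower and higher floors, the fit with unnamed transcripts kept and the fit without the array with the highest background were chosen only after the data were seen. All 26 main results (13 counts of genes, the response size with each siRNA and 11 FOXS1 differences) were tested in each alternative except the 2-fold minimum (the 13 counts) and the filter on all 18 arrays (15 results without the FOXS1 differences), and none changed its call or its count by over 1.5 times with no filter on dim probes, the mean of a gene's probes, outlier spots kept, unnamed transcripts kept or the highest-background array left out. Of 165 values of named genes, 150 kept their call with the authors' values, 13 lost it and 2 reversed, and 139 kept it in fits on only the arrays compared. Of 62 list calls, 55 to 62 kept their call in each alternative that left no array out. With 1 array left out 352 of 432 list calls were kept, 75 lost and 5 reversed, and with 1 slide left out 164 of 186 were kept and 22 lost. For named genes 942 of 1056 and 401 of 495 were kept and 114 and 94 lost. The replicate block lost 3 list calls, given with their lists, and changed no other call of a named gene or FOXS1 difference. Where not stated otherwise, the cause of a change was not tested. Dim spots set the limit: FOXS1 with siFOXS1-2 in BSA lay at the floor, and the filter for spots above background on all 18 arrays removed FOXS1, so it gave no FOXS1 value.

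With the replicate block, which removes the spread between slides, the counts were 3177, 4870 and 2512 for TGFβ1 with siNC, siFOXS1-1 and siFOXS1-2. They were 8060 and 6748 for siFOXS1-1 and siFOXS1-2 in BSA, 8324 and 7084 in TGFβ1, 6831 and 7581 for the siRNAs against each other, 64 for the interaction with siFOXS1-1, and 4155 and 4128 for genes shared by both siRNAs in BSA and TGFβ1. With a 2-fold minimum, which is stricter by construction, they were, in the same order, 155, 331 and 79, then 467 and 251, 566 and 276, 251 and 387, 4, and 125 and 120. Fits on only the arrays compared, which have fewer samples, gave 313, 869 and 10 for TGFβ1, 1221 for siFOXS1-2 in TGFβ1, 1819 for the siRNAs against each other in TGFβ1, 4 and 0 for the interactions and 1088 shared genes in TGFβ1. There the response size with siFOXS1-2, -0.074, passed its test by fry, and the FOXS1 differences for TGFβ1 with siFOXS1-2 (2.16; adjusted p = 0.0747) and between the siRNAs in TGFβ1 (2.19; adjusted p = 0.0520) did not.

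The interaction counts for siFOXS1-1 and siFOXS1-2 were 5 and 0 with normexp, 0 and 0 with the filter on all 18 arrays, which tests fewer genes, 0 and 0 with a variance trend and robust eBayes, 0 and 0 with the authors' values, and 0 and 0 with the lower floor. Quantile normalization gave 1 for siFOXS1-2. FOXS1 with TGFβ1 in siFOXS1-2 cells was 0.88 with normexp (adjusted p = 0.156) and 1.16 with the higher floor (adjusted p = 0.161). FOXS1 between the siRNAs in BSA was 0.57 with normexp (adjusted p = 0.202) and 0.31 with the higher floor (adjusted p = 0.673). Both pairs of groups include one at the floor, so the floor sets the size. The interaction values that reversed with the authors' values were -0.43 for LDLRAD4 and -0.16 for MST1R with siFOXS1-1. List means that reversed when 1 array was left out all belong to the interaction with siFOXS1-2. Interferon-stimulated genes ranged from -0.034 (without siFOXS1-2 BSA array 3) to 0.32. NF-κB targets ranged from -0.051 (without siNC TGFβ1 array 1) to 0.27 and were at -0.034 without siFOXS1-2 TGFβ1 array 2. Cholesterol synthesis genes ranged from -0.21 to 0.0014 (without siFOXS1-2 BSA array 1) and were at 0.00073 without siFOXS1-2 TGFβ1 array 3.

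Leaving out 1 array or 1 slide gave 70 to 605 genes for TGFβ1 with siNC, 332 to 1770 with siFOXS1-1 and 35 to 306 with siFOXS1-2. It gave 2575 to 4120 and 1271 to 2645 for siFOXS1-1 and siFOXS1-2 in BSA, 2669 to 4405 and 1184 to 3175 in TGFβ1, 1239 to 2684 and 1814 to 3524 for the siRNAs against each other, 0 to 20 and 0 to 5 for the interactions, and 761 to 1668 and 642 to 1793 for shared genes. Each lowest count except those of the interactions came without slide 2. Counts also moved by over 1.5 times without slide 1, to 400 and 190 for TGFβ1 with siNC and siFOXS1-2, 1860 and 1963 for siFOXS1-2 in BSA and TGFβ1, 1796 and 2394 between the siRNAs, and 1110 and 1159 for shared genes, and without slide 3, to 459 and 92 for TGFβ1. Single arrays did so for TGFβ1 with siNC (BSA arrays 1 and 2, 482 and 404; TGFβ1 arrays 2 and 3, 484 and 466) and with siFOXS1-2 (BSA arrays 1 to 3, 216, 164 and 169; TGFβ1 array 3, 177). For the interaction with siFOXS1-1, 10 of the 12 arrays moved the count to between 3 and 5, or to 20 without siFOXS1-1 TGFβ1 array 1, and slides 2 and 3 to 1 and 0. For siFOXS1-2 it went to 5 without TGFβ1 array 2 or 3, to 0 without slide 1 and to 1 without slide 3.

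The response size ranged from 0.090 to 0.19 with siFOXS1-1, where it failed its test in 5 of 15 fits, and from -0.11 to -0.029 with siFOXS1-2, where it passed without siNC BSA array 1 (-0.093) or slide 1 (-0.085). FOXS1 with TGFβ1 ranged from 3.07 to 3.56 with siNC (adjusted p = 0.0582 without slide 2), from 2.56 to 3.61 with siFOXS1-1 and from 1.95 to 2.47 with siFOXS1-2 (adjusted p = 0.287 without slide 2 and 0.124 without slide 3). It ranged from -3.38 to -3.01 and -4.69 to -4.33 for siFOXS1-1 and siFOXS1-2 in BSA, and from -3.80 to -2.91 and -5.88 to -5.35 in TGFβ1. Between the siRNAs it ranged from 1.13 to 1.47 in BSA, where each array of either siRNA except siFOXS1-1 array 3, and slides 2 and 3, ended the call (adjusted p up to 0.284), and from 1.86 to 2.75 in TGFβ1 (adjusted p = 0.0535 without slide 2). The interactions ranged from -0.63 to 0.26 and from -1.40 to -0.88, the latter with BSA arrays at the floor. A slide left out leaves 2 arrays per group.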

Other observations

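The comparisons described here were singled out only after the results were seen, and the gene lists were planned; no test was added.

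Values of single members of lists that were not called are given here as values only, since 1866 of 14486 genes were called in the same direction with both FOXS1 siRNAs in BSA. In BSA, with siFOXS1-1 and then siFOXS1-2, the TGFβ family had 6 higher and 3 lower and 4 and 4 of 34, integrins 4 and 2 and 2 and 2 of 16, and epithelial markers 3 and 5 and 2 and 3 of 19. Autophagy and lysosome genes had 7 and 3 and 5 and 3 of 21, p53 targets 7 and 2 and 4 and 2 of 22, hedgehog and notch genes 1 and 3 and 2 and 4 of 17, and forkhead genes 1 and 4 and 0 and 5 of 29. The lower forkhead genes include FOXS1, the target of the siRNAs. Adjusted over the lists alone only counts of siFOXS1-2 differed, with 4 and 5 for the TGFβ family, 6 and 3 for autophagy, 5 and 3 for p53 and 2 and 5 for hedgehog and notch genes. Of their members, the SMAD signal transducer SMAD4 fell (log2 -0.63 and -0.61), the integrin chain ITGA6 rose (1.88 and 1.69) and ITGB6 fell (-0.78 and -1.42). The junction genes TJP1 (0.98 and 1.13) and CLDN1 (1.02 and 0.99) rose while the keratin KRT7 fell (-0.51 and -0.67). The follistatin-like gene FSTL1 (1.90 and 0.66), the autophagy genes BECN1 (0.73 and 0.92) and WIPI1 (0.71 and 0.55), and the p53 targets TNFRSF10B (0.64 and 0.42), TIGAR (1.07 and 0.71) and ZMAT3 (0.66 and 0.66) rose. The notch target NRARP fell (-1.62 and -0.51). Of 13 siRNA machinery genes, siFOXS1-1 raised 4 and lowered 1 (5 and 1 adjusted over the list alone; adjusted p = 0.360 for the list), including AGO4 (1.02), and siFOXS1-2 raised TNRC6A (0.39) and AGO4 (0.37). With siFOXS1-2 the receptor NOTCH2 (-0.73) and the forkhead gene FOXO3 (-0.82) fell and HMOX1 (1.15) rose. Leukocyte and endothelial markers, lists of other cell types, were not called with either siRNA.

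Genes that the siRNAs moved in opposite directions under both treatments numbered 90, of which 60 were higher with siFOXS1-1 and 30 with siFOXS1-2. The gene with the largest of the smallest changes was INSIG1, a sterol-regulated brake on cholesterol synthesis (1.09 and -1.54 in BSA, 1.13 and -1.64 in TGFβ1, for siFOXS1-1 and siFOXS1-2), followed by the interferon-induced IFI44 (-1.05 and 1.10 in BSA, -1.35 and 1.16 in TGFβ1).

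Further lists were called for TGFβ1 in silenced cells, and lost the call with an estimated correlation. In siFOXS1-1 cells contractile genes had 9 of 21 higher and 1 lower (also adjusted over the list alone; median 0.35; adjusted p = 0.170 with an estimated correlation), proteases 6 of 20 higher and 2 lower (7 and 2 adjusted over the list alone; median 0.32; adjusted p = 0.170 with an estimated correlation), and mesenchymal markers 4 of 11 higher (adjusted p = 0.0598 with an estimated correlation). Transcription factors of epithelial-mesenchymal transition had 4 of 12 higher and 1 lower (adjusted p = 0.192 with an estimated correlation), cholesterol synthesis genes 2 of 24 higher and 1 lower (adjusted p = 0.656 with an estimated correlation) and NRF2 targets 2 of 20 lower (adjusted p = 0.478 with an estimated correlation). Called there only with the replicate block were epithelial markers (2 of 19 higher and 8 lower; adjusted p = 0.0527 without it and 0.0207 with it), hepatocyte genes (0.0749 and 0.0406) and NF-κB targets (0.0527 and 0.0194). In siFOXS1-2 cells contractile genes (4 of 21 higher, 1 lower; adjusted p = 0.172 with an estimated correlation), proteases (3 of 20 higher, 1 lower; adjusted p = 0.247) and hedgehog and notch genes (none called; adjusted p = 0.172) had positive medians. DNA replication (median -0.12), G2/M (-0.10) and interferon-stimulated genes (-0.23) had negative ones (adjusted p = 0.724 for each, with an estimated correlation). Mesenchymal markers (adjusted p = 0.0511 without the block and 0.0258 with it) and NRF2 targets (0.0511 and 0.00665) were called there only with the block.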
